A study of Zea mays with 6 samples.

How the data were processed

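Total RNA from whole maize plants was measured in 6 libraries, 3 labelled susceptible and 3 labelled resistant, both groups treated with Streptomyces murinus per the labels. Groups and replicate numbers were taken from the labels. The labels' protocols describe extraction with TRIzol and a library made by enriching small RNAs and ligating adapters, while the table gives values for whole genes; the labels do not resolve this, and the aligner, the counting tool and the genome build are not given in the sources used here.

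The authors deposited 1 table with whole-number counts per gene and library, per the file headers, and with FPKM per gene and library, per the file headers. It also holds the FDR, an adjusted p-value, and the log2 fold change of the authors' own comparison, per the file headers; the test behind them is not given in the sources used here. The sign of that deposited log2 fold change is susceptible over resistant in each of the 3786 genes, as read from the FPKM. Here all fold changes are resistant over susceptible. The table has 3787 lines below its header, of which 1 is the overflow of another line's annotation and was left out. Since each remaining gene carries an FDR of at most 0.00998 in the authors' deposited table, the table is a list of called genes. Enrichment against all maize genes was not tested, column totals are not library sizes, and scalings that assume mostly unchanged genes do not hold on it.

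Relative depth was therefore computed from the ratio of count to FPKM, which for 1 gene is proportional to library size. The median ratio to susceptible replicate 1 was taken over genes with at least 50 counts in both libraries, 1610 to 2664 genes per library, and depths were centred on their geometric mean. The design fixed before the data were examined had named TMM; depth was put in its place once the table was seen to hold called genes, and TMM was kept as an alternative. With this depth, the log2 fold changes in the authors' deposited table, with the sign turned, lay a median of 0.067 above the log2 ratios of depth-scaled mean counts, over 1806 genes with at least 20 counts in each library.

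Counts were tested with edgeR 4.0.16 in R 4.3.3 (glmQLFit and glmQLFTest, filterByExpr, group as the only term, Benjamini-Hochberg adjustment over 3786 genes, called at an adjusted p under 0.05). The filter removed 0 genes. The SE printed beside a log2 fold change is its size divided by the square root of the F statistic. Alternatives were DESeq2 1.42.0, limma-voom with limma 3.58.1, other scalings and filters, a block by replicate number, leaving out each library, thresholds on fold change, and glmTreat. Gene lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry. Python 3.11.15 with scipy 1.17.1, pandas 2.3.3 and numpy 2.4.6 was used for Fisher exact and permutation tests.

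The edgeR steps were tested on simulated data with the real means, depths and dispersions, in which 200 of the 3786 genes were changed. For resistant against susceptible they called 1 of 67 genes changed 1.5-fold, 6 of 67 changed 2-fold and 56 of 66 changed 4-fold, and 6 of 3586 unchanged genes. In the real data all 3786 genes were called, so the adjustment was much milder there and these rates do not carry over. The common biological coefficient of variation was 0.326. Replicates of a group differed by a chi-square of 24.5 to 83.5 per degree of freedom, so no library was a copy of another. Fold changes against a group with 0 counts were given as lower bounds at a floor of 3 counts over its 3 libraries. With 1 to 3 counts the ratio was given with an exact 95% counting interval, and both cover counting error only.

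In total 42 gene lists, covering hormones, defence, metabolism, nutrients, organ markers and reference functions, were fixed before the data were examined and matched by the annotation text; 40 had a member in the table and 28 had at least 5. The table holds no gene symbols, so genes are named by their identifiers and by the best-hit annotations it carries, which can point to a related gene. A reference gene table of assembly Zm-B73-REFERENCE-NAM-5.0 matched 1611 genes through those hits and gave 7 of them a symbol that was not a locus number, and it was used for list matching and for the chromosomes of neighbouring genes; no coordinates are given.

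Genes named in the text follow a rule fixed before the data were examined. It takes the 6 largest and 6 smallest log2 fold changes among called genes with a mean of at least 5 CPM of the listed counts, no overlap between the groups and an informative annotation. It also takes, for each list, the 2 called members with the smallest adjusted p in each direction, of which those of lists that did not pass the set test may be left out, and the gene annotated as PIN-LIKES 3.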

Results

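RNA from whole maize plants (Zea mays) was measured in 6 libraries, 3 from a group labelled susceptible and 3 from a group labelled resistant. Per the labels, both groups had been treated with Streptomyces murinus, a filamentous soil bacterium. The only comparison that could be made was resistant against susceptible, and an effect of the treatment itself could not be measured without untreated libraries. The labels state neither what the plants resisted nor whether the replicates were separate plants, so p-values measure the spread between these libraries, which may be technical. Counts and FPKM (fragments scaled to transcript length and library size) were given for 3786 genes, of which 2423 had reference maize identifiers (Zm00001eb) and 1363 had identifiers of new genes (NewGene). In the authors' deposited table, the largest FDR was 0.00998 and the smallest absolute log2 fold change was 0.59, so it holds genes that had already been called. The listed genes held between 2064057 and 2553185 counts per library. Relative sequencing depth, taken from the ratio of counts to FPKM, ran from 0.868 to 0.989 in the susceptible libraries and from 0.945 to 1.27 in the resistant libraries.

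The comparison asks which genes differed between resistant and susceptible plants that had received the same bacterium. Auxin repressor genes, 2 auxin synthesis genes, most secretory peroxidase genes and most intracellular immune receptor genes in the table were lower in the resistant group. So were 4 of 5 genes matched by name to a root marker list. Most genes of the phenylpropanoid and lignin list, and 7 of 9 genes of the gibberellin list, were higher there. The broader annotated pathway of phenylpropanoid biosynthesis was split, with 15 genes higher and 14 lower. The 2 auxin synthesis genes were too few for a set test, and none of the other lists passed one against the other listed genes after adjustment. Of the 3786 listed genes, 1756 were higher in the resistant group and 2030 were higher in the susceptible group (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). Spearman correlations across the listed genes were 0.957 to 0.981 between libraries of one group and 0.267 to 0.327 between groups; genes are not independent replicates. All listed genes had been selected for a difference between the same libraries, so these calls are not independent evidence of it. That selection also lowers the correlations between groups, which do not measure how far maize genes as a whole differed.

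Transcripts of 944 genes were counted in only 1 of the groups. Of these, 486 had no count in any susceptible library and 458 had no count in any resistant library. They made up 646 of the 1363 new genes (47.4%) and 298 of the 2423 reference genes (12.3%). Among those with an informative annotation that met the naming rule, the largest such difference was in NewGene_17546. It is annotated as a BED zinc finger protein of the RICESLEEPER family, which derives from transposases. It stood at 399 ± 41.2 FPKM (SD, n = 3) in the susceptible group with 0 counts in the resistant group, and was at least 41400-fold lower there. All lower bounds are set against a floor of 3 counts over the 3 libraries of the group at 0 and cover counting error only. NewGene_17548, NewGene_3481 and NewGene_1642, which carry annotations of the same family, were at least 8856-fold, 5070-fold and 1542-fold lower in the resistant group. Zm00001eb391860, annotated as a DEAD-box RNA helicase, and Zm00001eb075600, annotated as the nuclear pore protein NUP96, were at least 3060-fold and 1372-fold lower. Of 3 listed genes with the name of this helicase, the other 2 were higher in the resistant group. The log2 ratio of FPKM summed over the 3 was -1.19, so a split of reads between them remains open.

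In the other direction, Zm00001eb002810, annotated as glutathione S-transferase F11, stood at 40.7 ± 9.95 FPKM (SD, n = 3) in the resistant group with 0 counts in the susceptible group, at least 1648-fold higher. Zm00001eb233510, annotated as fiber protein Fb15, was at least 1483-fold higher at 119 ± 17.7 FPKM. NewGene_19535, annotated as a MYB4R1 domain protein, was at least 1158-fold higher. Zm00001eb345650, annotated as a guanosine nucleotide diphosphate dissociation inhibitor, a regulator of vesicle transport, was at least 879-fold higher. NewGene_27348, annotated as an alpha tubulin, was at least 778-fold higher. NewGene_8173, annotated as a knotted-1-like homeobox protein, a family known from shoot meristems, reached 86.0 ± 9.11 FPKM in the resistant group. Its 3 counts in the susceptible group all lay in replicate 3, which gives a ratio of 7777 with a 95% counting interval of 2661 to 37710 (exact binomial); its fitted log2 fold change of 12.78 became 16.09 without that library.

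Genes of auxin signalling, which controls growth and root formation, were mostly lower in the resistant group. All 7 listed Aux/IAA genes, which encode repressors that auxin itself induces, were lower in the resistant group under each of the 4 scalings. Their median log2 fold change was -2.65 with the depth used here, -2.47 with listed totals, -2.27 with TMM and -1.86 with DESeq2 size factors, where 6 of the 7 were called. Zm00001eb031190, annotated as IAA31, stood at 79.8 ± 18.3 FPKM (SD, n = 3) in the susceptible group and 6.17 ± 0.942 FPKM in the resistant group (edgeR log2 fold change -3.78 ± 0.25 SE, adjusted p = 1.88e-05). Zm00001eb200190 and Zm00001eb056750 had log2 fold changes of -4.43 and -4.72, but both stayed under 1 FPKM in the mean and share 1 best-hit maize protein, so their split of reads is uncertain; the latter gene was chosen after its values were seen. The gene annotated as PIN-LIKES 3, an auxin carrier of the endoplasmic reticulum (Zm00001eb316860), stood at 2.31 ± 0.557 FPKM in the susceptible group and 0.503 ± 0.123 FPKM in the resistant group (edgeR log2 fold change -2.18 ± 0.38 SE, adjusted p = 0.000767). Both listed YUCCA genes, which encode the last step of auxin synthesis, were lower as well. Zm00001eb419450 had a log2 fold change of -2.40 ± 0.21 SE. Zm00001eb098150 had -3.37 ± 0.84 SE, which became -4.58 without resistant replicate 2 and -2.68 without susceptible replicate 3. Root marker genes were also mostly lower, with a log2 ratio of summed FPKM of -1.67 against -1.68 for Aux/IAA genes, but a median over members of -1.48 against -2.65 and 1 member at 4.68 (9.08 without susceptible replicate 1). A different share of root tissue was therefore not separated from these differences.

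**Figure D1:**
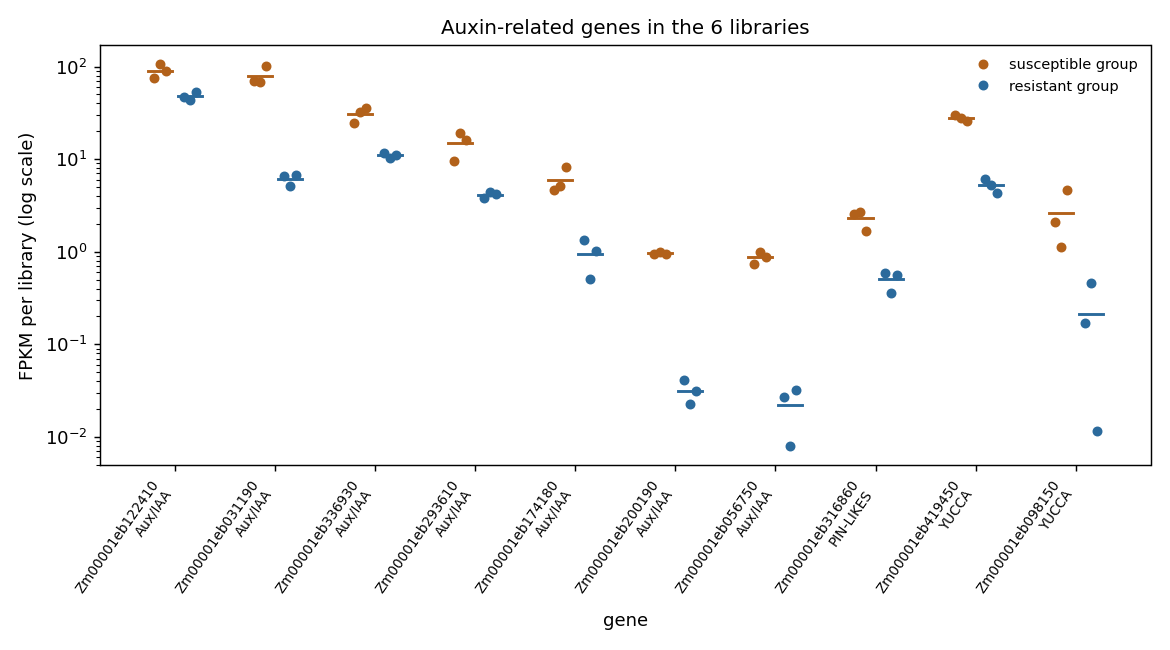
FPKM of the listed Aux/IAA, PIN-LIKES and YUCCA genes in each library on a log axis; points are libraries (3 per group) and short lines are group means. For each of the 10 genes, the 3 resistant libraries lie below the 3 susceptible libraries, and these genes had been selected for a difference.

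Of 4 listed auxin response factor genes, 1 was higher and 3 were lower in the resistant group; with DESeq2 size factors 2 were higher and 2 lower. Zm00001eb035640, annotated as ARF21, had a log2 fold change of 0.94 ± 0.18 SE. Zm00001eb118970 (ARF1) and Zm00001eb157270 (ARF2) had -1.16 ± 0.24 SE and -1.01 ± 0.22 SE, and lost their calls with DESeq2 size factors in edgeR (adjusted p = 0.199 and 0.394). Among 6 early auxin-responsive SAUR and GH3 genes, 2 were higher and 4 lower. The GH3 gene Zm00001eb330350, annotated as an enzyme that conjugates auxin to amino acids, had a log2 fold change of -2.08 ± 0.34 SE.

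Most other hormone lists held members of both directions. Of 9 gibberellin genes, 7 were higher in the resistant group and 2 lower; the higher genes were a DELLA repressor, a 2-beta-dioxygenase, which inactivates gibberellin, and 5 with a GID1L2 receptor name whose Swiss-Prot hits are carboxylesterases and related enzymes, so their role in gibberellin response is uncertain. Zm00001eb373640, annotated as the DELLA repressor DWARF8, was counted only in the resistant group, at least 44.1-fold higher, while Zm00001eb219040, annotated as gibberellin 20-oxidase but with a flavonoid dioxygenase as its Swiss-Prot hit, had a log2 fold change of -1.79 ± 0.39 SE. Of 18 ethylene genes, 7 were higher and 11 lower (8 and 10 with DESeq2 size factors); Zm00001eb255160, annotated as the ethylene response factor RAP2-4, fell from 144 ± 23.2 to 41.4 ± 4.19 FPKM. Among 7 JAZ genes, which encode jasmonate repressors, 3 were higher and 4 lower. The TIFY10b genes Zm00001eb009620 and Zm00001eb168150 rose by log2 fold changes of 3.49 ± 0.34 SE and 3.55 ± 0.35 SE; they share 1 best-hit protein and have similar counts, so their split of reads is uncertain. The TIFY3 gene Zm00001eb056840 had -3.47 ± 0.35 SE. Jasmonate synthesis had 2 genes higher and 2 lower, abscisic acid 3 and 2, cytokinin 2 and 3, and salicylic acid 0 and 1, with the 1 gene, Zm00001eb420270, annotated as salicylic acid-binding protein 2 and at 22.1 ± 2.96 against 0.296 ± 0.181 FPKM. Of the 2 lower jasmonate synthesis genes, Zm00001eb054050 is annotated as a 9S-lipoxygenase, so its place in that pathway is uncertain. In the abscisic acid list, NewGene_21170 was lower and NewGene_21171 higher, the latter chosen after its values were seen. Both are annotated as 9-cis-epoxycarotenoid dioxygenase 1, and the log2 ratio of their summed FPKM was -0.819, so a split of reads between them remains open.

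Defence genes differed in both directions. Of 28 NLR genes, which encode intracellular immune receptors, 9 were higher in the resistant group and 19 lower, and 8 were counted in only 1 group. The summed NLR signal was 249 ± 102 FPKM (SD, n = 3) in the susceptible group and 58.2 ± 4.07 FPKM in the resistant group. Of these sums, Zm00001eb405880 alone, chosen after its values were seen, held 88.2 ± 49.3 and 18.0 ± 0.972 FPKM. Its highest count in the susceptible group, 7290, lay in replicate 2. Among the higher genes, Zm00001eb391100 and Zm00001eb422890 carry an ABC transporter name beside an RGA4 Swiss-Prot hit, so their place in this list is uncertain. Zm00001eb164630, annotated as RGA4, had a log2 fold change of -5.85 ± 0.42 SE. Zm00001eb115770 and Zm00001eb261570, both annotated as RPM1 by the protein database hit, were at least 72.4-fold and 49.8-fold higher in the resistant group. The Swiss-Prot hit of Zm00001eb115770 is Pik-2. Of 6 listed genes with the RPM1 name, the other 4 were lower, and the log2 ratio of FPKM summed over the 6 was -2.445. Of 3 listed genes with the RGA4 name, the other 2 were higher, with a summed log2 ratio of 0.559. A split of reads between genes of 1 name therefore remains open. Among 62 receptor-like kinase genes, 26 were higher and 36 lower. Zm00001eb266200, annotated as a cysteine-rich receptor kinase, was at least 357-fold higher, and Zm00001eb132630, annotated as a leucine-rich repeat receptor kinase, at least 351-fold lower. Pathogenesis-related proteins had 7 genes higher and 8 lower (8 and 7 with DESeq2 size factors), WRKY factors 4 and 4, MYB factors 9 and 10 (10 and 9 with DESeq2 size factors), and NAC factors 0 and 4 (2 of them called with DESeq2 size factors). Of 9 calcium and oxidative burst genes, 2 were higher and 7 lower; the respiratory burst oxidase gene Zm00001eb410380 (RBOHB) had a log2 fold change of -4.21 ± 0.48 SE, while Zm00001eb023090 (RBOHF) had 2.44 ± 0.41 SE, which became 3.04 without susceptible replicate 1.

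Genes of secondary metabolism and detoxification differed in both directions. Of the 10 genes of the phenylpropanoid and lignin list, 8 were higher in the resistant group and 2 lower. The broader annotated pathway of phenylpropanoid biosynthesis, tested after the results were seen, showed no such lean. It had 15 of 29 genes higher and 14 lower (Fisher exact p = 0.58, adjusted p = 0.78). The 4-coumarate-CoA ligase-like gene Zm00001eb365590 rose from 3.56 ± 0.405 to 9.01 ± 0.385 FPKM (SD, n = 3), while the phenylalanine ammonia-lyase gene Zm00001eb077220, the entry step of the pathway, had a log2 fold change of -1.91 ± 0.47 SE. Of 11 class III peroxidase genes, which encode secreted enzymes that also act on lignin precursors, 2 were higher and 9 lower; 1 of the lower members, Zm00001eb305120, has a receptor kinase as its Swiss-Prot hit and is also counted among the receptor-like kinases. Zm00001eb330580, annotated as cationic peroxidase 1, stood at 11.6 ± 6.03 FPKM in the susceptible group and 1.07 ± 0.0695 FPKM in the resistant group. Of 10 glutathione transferase genes, which encode detoxifying enzymes, 6 were higher and 4 lower (7 and 3 with DESeq2 size factors); Zm00001eb138300 rose from 2.05 ± 0.85 to 47.2 ± 11.8 FPKM. Flavonoid genes were split 6 and 9, cytochrome P450 genes 9 and 10, terpenoid phytoalexin genes 3 and 3 (1 of the lower members, Zm00001eb009160, is annotated as trehalose-6-phosphate synthase and is not a terpenoid gene), and benzoxazinoid genes, which make the main preformed defence compounds of maize, 1 and 2. Of the 2 lower benzoxazinoid genes, Zm00001eb060830 is annotated as a tryptophan synthase alpha chain, so its place in that pathway is uncertain. The gene annotated as BX6 (Zm00001eb373400) had a log2 fold change of 6.34 ± 0.78 SE, which became 7.59 without susceptible replicate 2, and the BX8-like gene Zm00001eb304040 had -1.95 ± 0.45 SE.

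Lists that mark organs or general cell functions were measured beside these groups. Of 5 root marker genes, 1 was higher in the resistant group and 4 lower (3 of the 5 called with DESeq2 size factors), with summed levels of 118 ± 17.1 FPKM in the susceptible group and 37.1 ± 3.19 FPKM in the resistant group (SD, n = 3). The higher one is annotated as CASP-like protein 4B4, and the lower ones include ROOT HAIR DEFECTIVE 3 homolog 1 and COBRA-like protein 7. They were matched by name and not by expression in roots, so how far they measure root tissue is uncertain. Nuclear photosynthesis genes had 2 members higher and 1 lower; the chlorophyll a/b-binding protein gene Zm00001eb161390 stood at 60.8 ± 32 FPKM in the susceptible group and 314 ± 126 FPKM in the resistant group. Both listed C4 cycle genes, new genes annotated as NADP-malic enzyme (NewGene_19059 and NewGene_2732), were counted only in the resistant group. Meristem markers were split 2 and 3, seed markers 1 and 2, and pollen markers 0 and 2. Of 52 cytosolic ribosomal protein genes, 25 were higher and 27 lower, and 16 were counted in only 1 group. Cell division genes were split 6 and 6 (7 and 5 with DESeq2 size factors), heat shock proteins 5 and 5, cell wall growth 3 and 2, nitrogen uptake and assimilation 5 and 4, iron uptake 3 and 3, phosphate starvation 6 and 6 (7 and 5 with DESeq2 size factors), and aquaporins 0 and 1. The brassinosteroid and organelle-encoded lists had 0 members in the table.

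**Figure D2:**
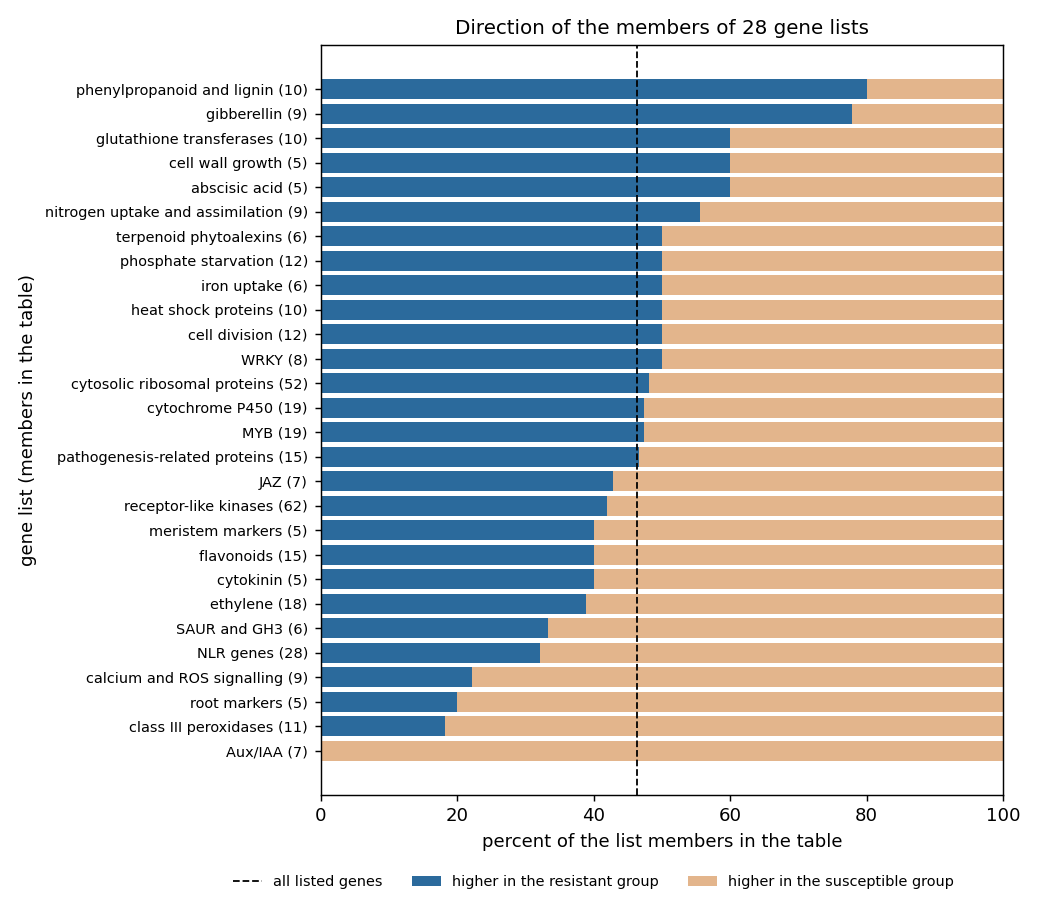
Percent of the listed members of each of 28 gene lists that were higher in the resistant group (dark) or in the susceptible group (light), with member numbers in brackets; the dashed line marks all listed genes, of which 46.4% were higher in the resistant group. Aux/IAA genes lie at 0% and phenylpropanoid and lignin genes at 80.0%.

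No list stood apart from the other listed genes after adjustment over the 28 lists with at least 5 members. In camera with a preset correlation of 0.01, 0 lists passed, and 2 passed unadjusted, Aux/IAA lower (p = 0.0249, adjusted p = 0.641) and glutathione transferases higher (p = 0.0458, adjusted p = 0.641) in the resistant group. With an estimated correlation 0 lists passed, and those unadjusted values became p = 0.309 and p = 0.105. A Fisher exact test of direction against the other listed genes, chosen after the table was seen, also passed 0 lists, and 1 unadjusted, Aux/IAA (p = 0.0173, adjusted p = 0.484). That test treats genes as independent, while camera estimated a correlation of 0.49 among the Aux/IAA genes, so its p may be too small. The fry test passed 20 lists, but it asks only whether members move on balance one way, which genes selected for a difference do readily. Because all listed genes were selected as different, the tests cannot compare a list with unchanged genes. The members called when adjusted over the list alone were in each list the same in number as those called over all genes. This outcome was fixed in advance, since each listed gene had an unadjusted edgeR p under 0.05.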

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

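The direction test, DESeq2 with its own size factors, and the fits without genes at 0 in 1 group or on reference genes were chosen after the data were seen. Of the 3786 genes called in edgeR, 3700 were called with TMM, 3775 with listed totals as library size, 3340 with DESeq2 size factors, 3785 with the DESeq2 Wald test at the same depth, 3393 with that test's own size factors and 3746 with limma-voom. Relative to the depth used, median log2 fold changes shifted by 0.383 with TMM, 0.18 with listed totals and 0.787 with DESeq2 size factors. The last gave 1756 genes higher and 1584 lower in the resistant group and turned the sign of 46 estimates, none of them called there. Filters on low counts removed no gene and so tested nothing. Leaving out 1 library gave 3754 to 3786 calls, and leaving out the 50 genes with most counts gave 3736 of 3736. Asking also for an at least 2-fold change left 3414 genes called, and glmTreat called 3001 genes. Reference genes alone gave 2422 calls, 1101 higher and 1321 lower, because fewer genes were tested; without genes at 0 in 1 group, 2841 of 2842 were called. The fry test passed 20 lists where camera passed 0, since it does not compare a list with other genes. A replicate block gave 3785 calls; deviations of same-numbered libraries correlated at 0.197, 0.103 and 0.038 across 2026 genes, so the numbers were not treated as pairing, and resistant replicate 3 correlated best with susceptible replicate 2. The block changed no list call. Over the named genes and these alternatives, 15 results lost the call in the same direction, 2511 did not, and 0 reversed. In 7 of these cases it was the lipoxygenase gene Zm00001eb206040. With 200 of the genes changed in simulation, 9% of the 2-fold changes were called. That rate does not carry over to the real data, where all genes were called and the adjustment changed little. There the lipoxygenase gene Zm00001eb206040 had an edgeR p of 0.0494 before and after adjustment.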

Other observations

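The tests of pathways and domains, the splits of the libraries and the 3 Aux/IAA tests were chosen after the results were seen; the outcomes that would count for or against the partner and neighbour tests were set before their values were computed.

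Annotated pathways were compared by the direction of their listed members against all other listed genes. Of 15 genes of glyoxylate and dicarboxylate metabolism, which includes photorespiration, 12 were higher in the resistant group and 3 lower (Fisher exact p = 0.0164, adjusted p = 0.498). Carbon fixation had 8 of 10 and porphyrin and chlorophyll metabolism 8 of 10 higher in the resistant group. RNA polymerase had 9 of 10 genes lower there (Fisher exact p = 0.0246), and ubiquitin-mediated proteolysis 18 of 24 (Fisher exact p = 0.0399). The largest relevant pathways leaned little, with 31 higher and 46 lower in plant-pathogen interaction and 28 higher and 41 lower in plant hormone signal transduction (Fisher exact, adjusted p = 0.746 for each). Of 50 pathways, 0 passed the adjustment and 3 passed unadjusted.

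Protein domains gave a similar picture. Genes with an NB-ARC domain, the nucleotide switch of immune receptors, were lower in the resistant group in 18 of 22 cases (Fisher exact p = 0.00888, adjusted p = 0.16), and those with a protein kinase domain in 39 of 56 (p = 0.0153, adjusted p = 0.16, Fisher exact). Genes with a PPR repeat, common in organelle RNA processing, were higher in 10 of 13 (Fisher exact p = 0.0468, adjusted p = 0.328). Of 21 domains, 0 passed the adjustment and 3 passed unadjusted. The Fisher tests of pathways and domains treat genes as independent. Neighbouring genes shared their direction more often than permuted ones, as given below, so these p-values may be too small. Of 13 genes annotated as 40S ribosomal protein S4-3, 8 were higher in the resistant group and 5 lower.

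In the edgeR test of all listed genes, the 6 libraries allow 10 splits into 3 and 3, which are too few for a share under 0.05. As large a count as in the real split (3786 genes) came from 1 split, the real one, with 0 in the others. Because the genes had been selected for a difference in that split, this outcome was set by the selection and says nothing about chance.

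Genes counted in only 1 group may reflect reads of 1 gene assigned to different gene models in the 2 groups. That would give them partners of the same best-hit name that are higher in the other group, yet 60 had one, against a median of 120 (95% range 105 to 136) in 1000 permutations of the directions. The permutations shuffle directions gene by gene, so genes of 1 name that move together lower this number whether or not reads were reassigned. The number therefore cannot decide on reassignment between listed genes of 1 name. Only 187 of the 944 genes share a name with any listed gene and could score, and single swaps among the 60 remain open. The 2 genes named outer arm dynein light chain 1 had a log2 ratio of summed FPKM of 0.014 (median absolute log2 fold change 8.302). The 3 named glyoxalase I-like protein had -5.21 (10.443), among 89 names with members in both directions. For the 884 without a partner, one under another name cannot be told apart from a true absence. Sequence differences between the genomes of the groups that lie in blocks are a candidate explanation: neighbouring reference genes of this kind (within 5 gene models in identifier order) shared their direction in 77.78% of 27 pairs, against a permutation median of 48.15% (upper limit of the central 95% of permutations 66.67%, permutation p = 0.0023), and in 72.73% of the 22 pairs without a shared name or Pfam domain (upper limit 68.18%). Neighbours with counts in both groups also agreed more often than permuted ones (64.1% of 546 pairs), so the agreement is not particular to genes at 0 in 1 group. The labels do not say whether the groups differ in genotype, and no reads were examined, so a source in genomic blocks is a hypothesis.

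Neighbouring listed reference genes shared their direction in 444 of 699 pairs (63.52%), against a permutation median of 50.36% (upper limit 54.08%, permutation p = 0.0001, the smallest that 10000 permutations can give). Tandem copies of 1 gene could produce this, but 62.35% of the 656 pairs without a shared name or Pfam domain also agreed in direction (upper limit 54.27%), which argues against tandem copies as the whole source. Pairs with counts in both groups agreed in 64.1% of 546 cases. Genomic blocks that differ between the groups, and shared regulation of neighbours, were not separated, and the longest run of listed neighbours with 1 direction was 5 genes, within the permutations (upper limit 6, highest 7). Identifier order stands in for position here: consecutive matched genes lay on 1 chromosome in 72.89% of cases, against 10.75% by chance. Within chromosomes the absolute value of the rank correlation of identifier and position was only 0.387 to 0.834. Positions came through best hits, which can point to a related gene.

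All 7 listed Aux/IAA genes were lower in the resistant group, which could come from the scaling between groups. Across the 4 scalings the highest median log2 fold change was -1.862, with 6 of the 7 called under that scaling (DESeq2 size factors) and 7 under the others. None of these 4 scalings therefore removed the difference. The largest of their median shifts over all listed genes was 0.787, so a larger error of scale was not tested. The lean of the table towards the susceptible group cannot be told apart from a feature of this family, since the Fisher exact test of direction gave an adjusted p of 0.484 over 28 lists, and the median of all listed genes stayed below 0 under each scaling (-0.165 with DESeq2 size factors). A different share of root and leaf tissue in the plants also stays open. Of 5 root markers, 4 were higher in the susceptible group (3 of the 5 called with DESeq2 size factors). In the resistant group 2 of 3 photosynthesis genes were higher, as were 8 of 10 in each of carbon fixation and porphyrin metabolism. Neither pathway passed its test (Fisher exact p = 0.0522 each). The 2 C4 cycle genes share 1 name and had 0 counts in the susceptible group, while the 3 photosynthesis genes had counts in both groups. They belong to the genes counted in only 1 group, so they cannot serve as 2 measures of leaf share. A response tied to resistance itself was not tested, because both groups received the bacterium and no untreated libraries were analysed here.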
